A study of Macaca mulatta with 8 samples.

How the data were processed

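Single nuclei of male rhesus macaques were sequenced in 8 samples, 4 from a pool of 2 control animals and 4 from a pool of 1 animal exposed to sevoflurane, with 10x Genomics 3' chemistry v3, per the labels. The deposited values are whole-number UMI counts per gene and nucleus, not normalised, in 1 matrix over all libraries, with Cell Ranger 3.1.0 as the software version per the file headers. The submitters' processing notes name CASAVA 1.8, Cell Ranger and Seurat without saying what each did. The genome build and annotation are not given in the sources used here, so no coordinates are printed. The matrix held 21748 genes (1625 of them with no count), 59749 barcodes and 139133491 values above 0, the highest 1932. A suffix from 1 to 8 on each barcode gives its library, and no source used here pairs suffixes with samples. No library was given a group, and the planned comparisons of sevoflurane with control were not run. A matrix that cannot be divided by sample counts as 1 sample, so no p-value was computed.

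Genes were named by the symbol in the files, or by a symbol table (17209 of the IDs are in it) where the files gave only an ID or gave 1 symbol to several IDs. ENSMMUG00000004314 was thus taken as GABRB1. Mitochondrial-encoded genes were not analysed here. The gene lists, 397 genes in 23 lists of which 371 genes are in the matrix and 22 lists have values, were fixed before the data were examined, as were the markers of 19 cell types (161 markers, 155 in the matrix), the comparisons, the calling rule and the rule for naming genes.

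Nuclei with at least 500 UMIs and 300 genes were kept (58220). Doublets were scored within each library: sums of 2 random nuclei were simulated, the score was the share of simulated doublets among 50 neighbours, and the highest scores were removed at 0.8% per 1000 nuclei, 219 to 750 nuclei or 4.18% to 7.75% per library. Counts were scaled to 10000 per nucleus and log-transformed as log(1 + x). The 2000 most variable genes among those seen in at least 0.5% of nuclei were scaled, limited to 10 SD, and reduced to 30 principal components. Listed genes were left out of this step so that they did not define the classes. A graph of shared neighbours (20 per nucleus) was clustered with the Leiden method at resolution 1.0 with seed 1, without correction between libraries, and gave 43 clusters.

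Each marker was scaled from 0 to 1 over clusters, and a cluster took the type with the highest mean among types with enough markers. This scoring was settled after the data had been seen; the markers were not changed. A name needed at least 3 markers over 0.5 and a lead of 0.1 over the next type, with marker levels of at least 20 counts per 1000000 (CPM) (10 for granule and pyramidal subclasses) and at least 50 nuclei. No lead was asked within the oligodendrocyte lineage, between inhibitory and Cajal-Retzius neurons, or between fibroblasts and mural cells. Cluster 8 (1794 nuclei) was thus named inhibitory at a score of 0.712, although Cajal-Retzius neurons scored 0.734 from fewer than 3 markers over 0.5. Among their 10 leading genes, some clusters hold a marker of another type and none of their own: PROX1 (granule) in the immature cluster 6, CD96, F13A1 and FOXP2 in excitatory clusters 10, 16 and 25, and ENPP6 (newly formed oligodendrocyte) in the oligodendrocyte cluster 36. Their names rest on their marker sets. A pyramidal-like cluster needed 4 markers. A cluster stayed unnamed if its median doublet score was at least 0.5, or if its nuclei had a median UMI count under 1/3 of their library's with no own marker among the 10 leading genes. Of the 3 unnamed clusters, cluster 15 (1462 nuclei, median 927.5 UMIs) had low counts and made up 2.03% to 3.68% of each library, cluster 30 (576 nuclei; 0.0997% to 2.23%) resembled a pair of types, and cluster 32 (471 nuclei; 0% to 2.65%) had a doublet score of 0.62. Cluster 15 scored highest for excitatory neurons (0.861), but its 10 leading genes hold no excitatory marker. Excitatory clusters without enough granule or pyramidal markers stayed in the excitatory class only.

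UMIs were summed per class and expressed as CPM. A gene was measured if it reached 10 CPM in either class. It was called higher in a class if the ratio was at least 2-fold, the higher class reached 10 CPM and the direction was the same in every library with at least 50 nuclei in both classes. Intervals are exact 95% intervals (Poisson for CPM, the conditional binomial for ratios, Clopper-Pearson for shares). They cover counting error only. A list's median log2 ratio was ranked among 10000 random lists of equal size matched on mean expression (within 100 ranks). The genes open to being named were, for each comparison and list, up to 2 called genes of largest fold per direction, then over all lists the 8 called genes of largest fold and the 4 of highest CPM per direction, and every GABA-A subunit at 10 CPM or more in any class. The parts before the last gave 63, 51, 41, 52 and 60 genes for the 5 comparisons, to which the other GABA-A subunits are added, and the text prints part of them. Some listed genes count in the totals but are not reported here by name or drawn, and the search for libraries far from the others left them out.

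Calling was tested on simulated counts for each comparison, with 200 genes changed (50 at each of 4 folds) and 21548 unchanged. At 4-fold, 100% were recovered for neurons, excitatory, granule-like and astrocyte comparisons and 98% for oligodendrocytes. At 2.5-fold the oligodendrocyte comparison recovered 96% and the astrocyte comparison 86%, and the others 100%. Of genes changed 1.5-fold, 0% were called, which the 2-fold threshold sets, and unchanged genes were left uncalled. The simulation held counting error only, with the same profile in all libraries and changed genes above the 10 CPM minimum. It does not test calling where libraries differ beyond counting error, as they do here.

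Alternatives fixed before the data were examined were every barcode, at least 1000 genes per nucleus, doublets kept, Leiden resolutions 0.5 and 2.0, TMM factors, the median over libraries, 5% of the all-nuclei profile removed as free RNA, no minimum level, a 1.5-fold threshold, and each library left out. Leaving out any 4 libraries was added after the data had been seen. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, used for TMM factors only.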

Results

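Nuclei from frozen brain tissue of male rhesus macaques were profiled with droplet-based 3' RNA sequencing (10x Genomics chemistry v3), which counts RNA molecules per nucleus by unique molecular identifiers (UMIs). The sample characteristics name the hippocampus as the tissue, while the growth protocol names the amygdala, so the region is not settled by the sources used here. The treated animal breathed sevoflurane, an anaesthetic gas, at about 2.5 to 3%, for 4 h at each of 3 sessions. The first was at about postnatal day 7, and the wording of the other two (14 and 28 days) leaves open whether these are ages or intervals. Tissue of 2 control animals was mixed into 1 pool, and tissue of 1 exposed animal made up the other. Each pool was divided into 4 samples, so the 8 samples hold 4 controls and 4 exposed. The count matrix held 59749 nuclei and 21748 genes from 8 libraries, numbered here 1 to 8 by the suffix of their barcodes.

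The total per library ran from 35806547 to 47007082 UMIs, 331133661 in all. The median UMI count per nucleus of libraries 1 to 8 was 3412, 3426, 3274, 3189, 5730, 5816, 5831 and 5777. Filters left 58220 nuclei, of which 3576 were removed as doublets, and 54644 were kept, 5015 to 8931 per library. The filter on UMIs and genes removed nuclei only in libraries 5 to 8.

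The study's question was how sevoflurane exposure changes the cells of the primate hippocampus. No label or file used here ties a library suffix to a sample, so no library has a known group and sevoflurane was not compared with control. The comparisons that follow are between cell classes over all nuclei. They show where genes tied to anaesthetic action, synapses, metabolism and cell stress were expressed in tissue that includes both pools. The matrix counts as 1 sample: there are no replicates and no p-values. Intervals in parentheses are exact 95% intervals, Poisson for counts and Clopper-Pearson for shares, and cover counting error only. Libraries serve only as a check of direction: they are described as aliquots of 2 pools, not independent animals, so 8 of 8 libraries does not stand for 8 replicates.

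Neuron-like nuclei made up 52.2% of the 54644 nuclei (51.7–52.6), and non-neuronal nuclei 43.2% (42.8–43.7). Names of classes are short for "like" that type by its markers. Excitatory neurons were 35.5% (35.1–35.9), inhibitory neurons 12.8% (12.6–13.1) and immature neurons 3.86% (3.70–4.02). The immature class is cluster 6 alone, whose 10 leading genes include the granule marker PROX1 and none of the immature markers. Among excitatory neurons, dentate granule-like nuclei were 5.72% of all nuclei (5.53–5.92) and pyramidal-like nuclei 7.88% (7.65–8.11). Granule-like nuclei, by their markers a type of the hippocampal dentate gyrus, made up 3.25% to 10.3% of each library. This argues against amygdala tissue alone in any library, while a mixture with it stays open. Astrocytes were 14.1% (13.8–14.4), oligodendrocytes 11.4% (11.1–11.6), oligodendrocyte precursors 6.51% (6.31–6.72) and microglia or macrophages 5.43% (5.24–5.62). Ependymal cells were 2.16%, newly formed oligodendrocytes 1.85%, endothelial cells 0.857%, fibroblasts or mural cells 0.838% and cycling cells 0.163%. The remaining 4.59% (4.42–4.77), in 3 clusters, stayed unnamed. The libraries differed by far more than these intervals: neurons ranged from 29.9% to 71.9% (median 60.9%), oligodendrocytes from 1.12% to 25.4% (median 5.54%), immature neurons from 0.157% to 9.90% (median 1.82%), and astrocytes from 10.9% to 16.7% (median 15.0%). The libraries also differ in UMIs per nucleus and in what the filter removed, both of which can set shares, and a pooled share is an average over unequal libraries. Neurons held a mean of 7942 UMIs per nucleus and non-neuronal nuclei 2648.

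**Figure D1:**
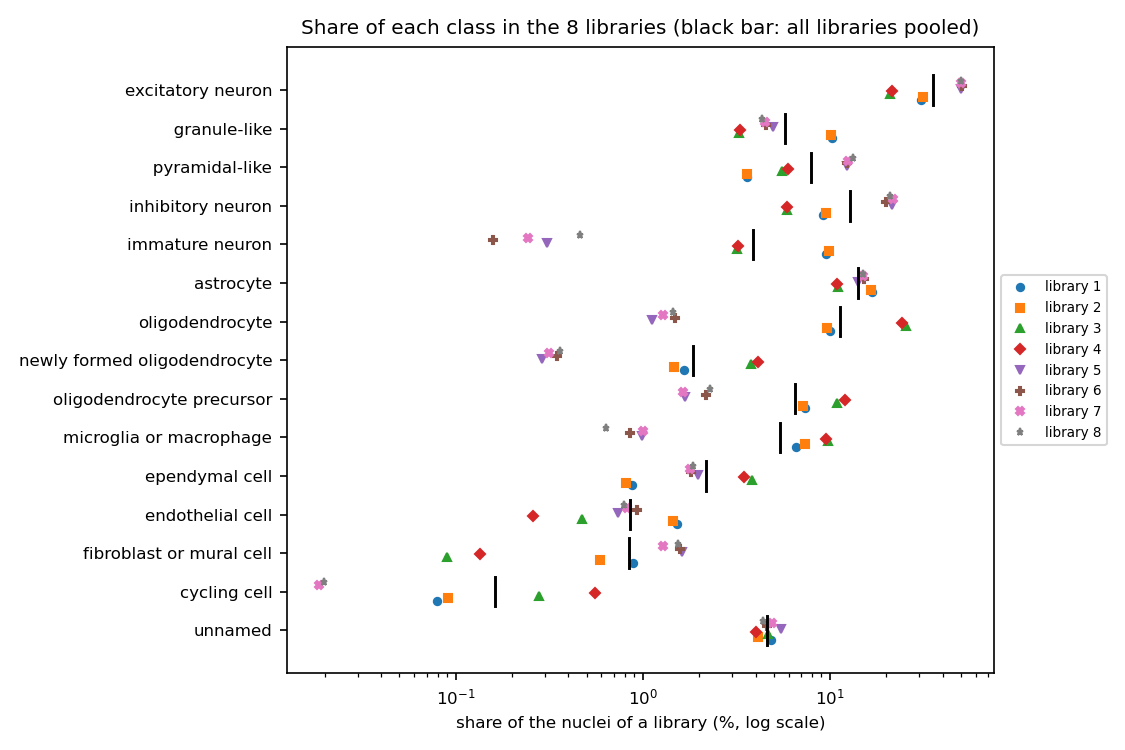
Share of nuclei per cell class, in percent on a log axis, with a point for each of the 8 libraries and a black bar for the pooled share. Shares of 0 are not drawn (cycling cells in libraries 5 and 6), and oligodendrocytes range from 1.12% to 25.4% while astrocytes stay between 10.9% and 16.7%.

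Neurons were compared with non-neuronal nuclei to place the listed genes in 1 compartment or the other. The NMDA receptor subunit GRIN1 stood at 70.5 counts per 1000000 (CPM) in neurons and 3.31 in non-neuronal nuclei, 21.3-fold higher (18.6–24.6). The guidance ligand SLIT3 was 14.5-fold higher in neurons (981 against 67.8 CPM; 14.0–14.9), the calcium channel gene CACNA1B 11.5-fold (759 against 65.8; 11.2–11.9), and the chloride exporter SLC12A5, which sets whether GABA inhibits, 10.8-fold (63.7 against 5.90). In the other direction the cytokine gene IL18 was 51.0-fold higher in non-neuronal nuclei (1.19 against 60.6 CPM; 45.1–58.0), and the lipid carrier APOE 12.5-fold (28.1 against 350.0; 12.1–12.8). All 6 went the same way in 8 of 8 libraries, with library 6 apart from the others for CACNA1B.

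Of 281 listed genes that reached 10 CPM, 101 were at least 2-fold higher in neurons with the same direction in every library, 61 were higher in non-neuronal nuclei, and 119 were neither. Under TMM scaling these counts were 115 in neurons and 46 in non-neuronal nuclei. A further 7 listed genes passed 2-fold but not in every library. Of all 10399 genes at 10 CPM, the same rule called 1224 higher in neurons and 1960 in non-neuronal nuclei. Vesicle release genes were higher in neurons for 15 of 16 measured, including SYT1, the calcium sensor of release (4.20-fold, 2649 against 631 CPM), and UNC13A, which primes vesicles (7.97-fold, 204 against 25.6). Sodium and calcium channels gave 18 of 22, with 1 the other way, and both lists had medians at percentile 100 of 10000 random lists of like expression. Also higher in neurons were 8 of 12 GABA-A subunits, 8 of 17 AMPA, kainate and NMDA subunits (1 lower), 5 of 8 metabotropic glutamate and GABA-B receptors (2 lower), 3 of 4 glycine and nicotinic subunits, 4 of 8 two-pore-domain potassium and HCN channels, 6 of 18 synaptic adhesion genes, 4 of 8 neurotrophin genes, 3 of 4 immediate early genes (1 lower), 15 of 28 axon guidance genes (5 lower) and 8 of 10 adenosine, opioid, cannabinoid, monoamine and acetylcholine receptors (1 lower). BDNF stood at 42.7 against 9.92 CPM (4.31-fold) and CNTNAP2 at 3727 against 567 (6.57-fold).

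Non-neuronal nuclei led for 8 of 9 complement and inflammatory genes (list median log2 ratio −4.38, percentile 0 of the random lists), 9 of 14 Wnt and Notch genes such as NOTCH1 (35.1-fold; 31.6–39.2; library 3 lay nearer to 0 than the others), and 8 of 14 cholesterol synthesis genes. Among the last, IDI1, an early enzyme of the pathway, stood at 145 CPM against 23.4 in neurons (6.21-fold), and INSIG1, which holds the pathway in check, was 6.37-fold higher (5.92–6.87). Glycolysis and lactate transport genes gave 7 of 19 higher in non-neuronal nuclei and 1 in neurons, including hexokinase HK2 (42.1-fold; 34.8–51.4) and the glucose carrier SLC2A1 (7.18-fold; 6.65–7.76). Chloride and GABA homeostasis gave 4 of 9 (1 in neurons), neurodegeneration risk genes 5 of 13 (1 in neurons), and steroid and thyroid receptors 1 of 11 in each direction. Of the stress and respiratory lists, 5 of 12 unfolded protein and heat shock genes, 2 of 11 apoptosis genes and 1 of 14 respiratory chain genes were higher in non-neuronal nuclei and none in neurons. The chaperone HSPA8, at 75.3 CPM (3.01-fold; 2.89–3.13), the calcium-binding chaperone CALR (2.62-fold), the survival gene MCL1 (2.69-fold) and the respiratory subunit NDUFA4 (2.72-fold; 2.62–2.83) are of this kind. The 8 called genes of these 3 lists stood higher still in the unnamed cluster with the fewest UMIs per nucleus, by a median ratio of 4.57 to non-neuronal nuclei, and the call for NDUFA4 ended when libraries were weighted equally. TMM scaling shifted the median of all genes by 0.23 on the log2 scale and ended 15 of the 162 calls, and it kept the direction of every gene named here. Taking 5% of the profile of all nuclei off each class as free RNA widened the folds of GRIN1, SLIT3, CACNA1B, SLC12A5, IL18, NOTCH1 and HK2 by over 1.5 times. Removing the same share from both classes can only widen a ratio. The equal weighting brought IL18 to a log2 ratio of −4.72 and HK2 to −4.80.

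**Figure D2:**
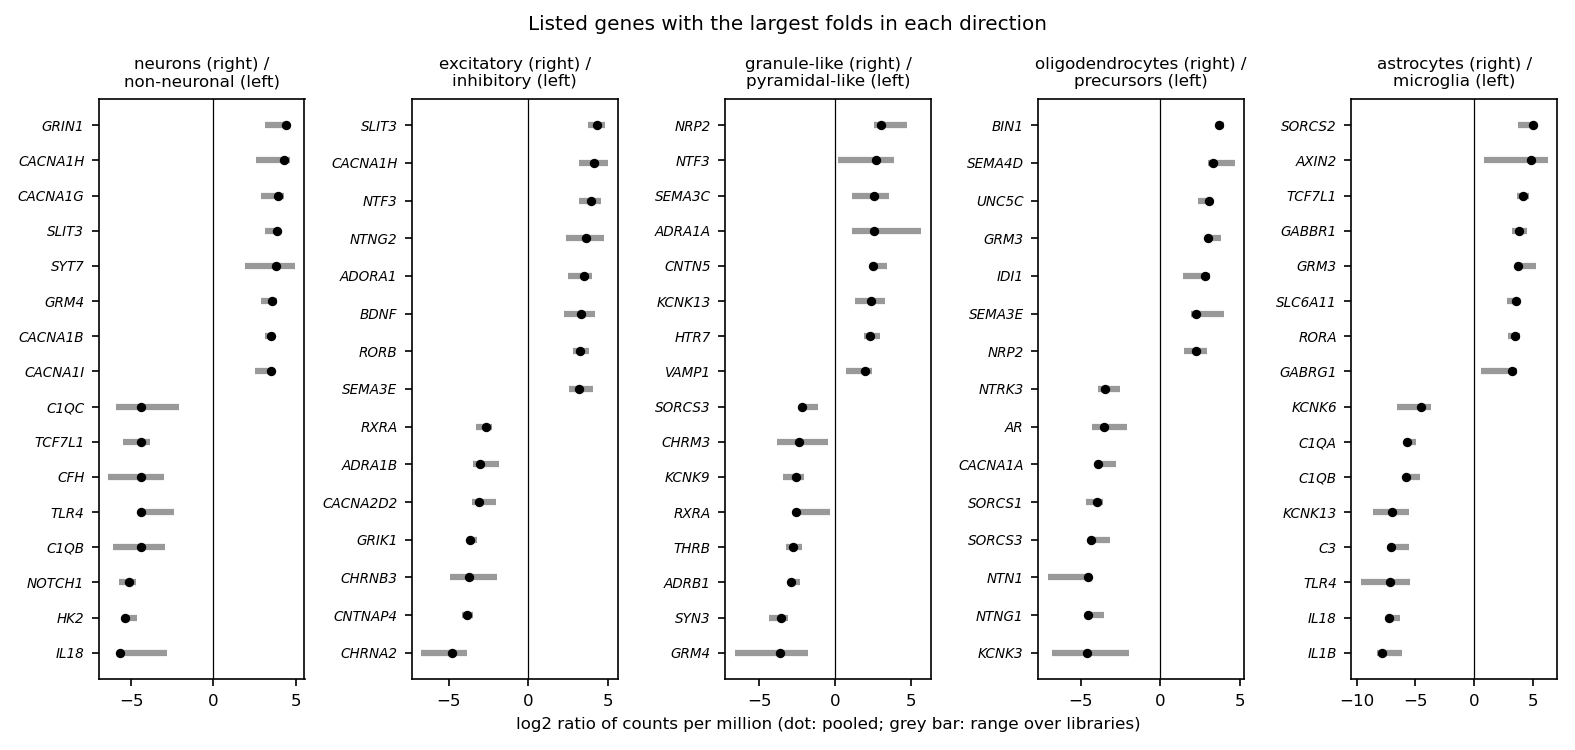
Log2 ratio of pooled CPM for up to 8 called genes of largest fold per direction in each of the 5 comparisons; dots are pooled ratios and grey bars the range over libraries (computed with a count of 0.5 added). Each dot lies past a 2-fold difference; GRIN1 is 21.3-fold higher in neurons, IL18 is 51.0-fold higher in non-neuronal nuclei, and C3 is 133-fold higher in microglia than in astrocytes.

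Excitatory and inhibitory neurons were compared because sevoflurane acts on both excitatory and inhibitory transmission. SLIT3 was 20.6-fold higher in excitatory neurons (1201 against 58.4 CPM; 19.8–21.4), the adenosine receptor ADORA1 11.4-fold (48.2 against 4.24; 9.81–13.3) and the neurotrophin BDNF 10.1-fold (52.1 against 5.14; 8.87–11.7). In inhibitory neurons the kainate receptor subunit GRIK1 was 12.6-fold higher (3140 against 249 CPM; 12.5–12.8) and the NMDA receptor subunit GRIN3A 6.17-fold (390 against 63.2; 6.03–6.32). Each held in 8 of 8 libraries.

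Of 265 measured genes, 36 were higher in excitatory and 36 in inhibitory neurons, and 193 were neither. Among all 9467 genes measured, listed or not, 584 were higher in excitatory and 609 in inhibitory neurons. Excitatory neurons led for 11 of 28 axon guidance genes (3 for inhibitory), among them NTNG2 (12.5-fold; 10.9–14.4) and SEMA3E (9.06-fold), and for 3 of 8 neurotrophin genes (1 for inhibitory), where NTF3 was 15.7-fold higher (12.3–20.3) and the list's median lay at percentile 100 of random lists. They also led for 5 of 22 sodium and calcium channels (1 lower), 2 of 17 vesicle genes (1 lower), 2 of 15 neurodegeneration genes, 2 of 3 immediate early genes and 2 of 9 two-pore-domain potassium and HCN channels (1 lower). HOMER1, a scaffold of glutamate synapses, stood at 597 against 199 CPM. Inhibitory neurons led for 7 of 17 AMPA, kainate and NMDA subunits (1 lower), including GRIK2 (4370 against 1423 CPM, 3.07-fold), 4 of 6 glycine and nicotinic subunits (1 lower), 3 of 18 adhesion genes such as CNTNAP4 (14.0-fold), 3 of 8 chloride and GABA genes including ABAT, which breaks GABA down (2.79-fold), and 4 of 10 adenosine to acetylcholine receptors (2 lower). By its median, the AMPA, kainate and NMDA list leaned to neither class (log2 ratio 0.0851, percentile 46.1 of random lists). Metabotropic and GABA-B receptors gave 1 of 8 in each direction, steroid and thyroid receptors 1 and 2 of 10, and apoptosis and Wnt and Notch genes 1 each in inhibitory neurons, of 9 and 10. No gene was called among 14 respiratory chain, 17 glycolysis, 12 cholesterol and 11 heat shock genes, or for the 1 measured complement gene, so these lists held no 2-fold difference between the neuron classes under this rule.

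GABA-A receptor subunits, through which sevoflurane prolongs inhibitory currents, split between the neuron classes. GABRA5, the subunit of extrasynaptic receptors of pyramidal cells, stood at 92.1 CPM in excitatory and 21.5 in inhibitory neurons (4.29-fold; 4.01–4.59). Among excitatory neurons, GABRA5 was higher in granule-like nuclei (136 CPM) than in pyramidal-like nuclei (71.5). GABRA2 stood at 437 against 219 (2.00-fold; 1.96–2.04), a call that ended without library 1 or 2 (log2 ratio 0.98 and 0.97) and when libraries were weighted equally (0.98). Inhibitory neurons held more GABRG3 (921 against 440 CPM) and GABRD (43.1 against 21.6). Under TMM scaling, which shifted all genes by a median of 0.10, both calls ended, with log2 ratios of −0.97 and −0.90. GABRD also fell short of 2-fold when library 3, 5, 6, 7 or 8 was left out (−0.95 to −0.99). GABRB2 was 1.64-fold higher in inhibitory neurons (561 against 342 CPM), and GABRA3, GABRA4, GABRB1 and GABRG1 were also neither.

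Granule-like neurons of the dentate gyrus were compared with pyramidal-like neurons, the 2 main excitatory types of the hippocampus. The semaphorin receptor NRP2 was 8.25-fold higher in granule-like neurons (7.65–8.91; 19.8 CPM in pyramidal-like neurons), and BDNF stood at 103 against 30.5 CPM (3.39-fold; 3.16–3.63). The adhesion gene CNTN5 stood at 933 against 168 CPM and the serotonin receptor HTR7 at 159 against 31.7. In pyramidal-like neurons the synapsin SYN3 was 11.6-fold higher (364 against 31.4 CPM; 10.7–12.5), the thyroid hormone receptor THRB 6.68-fold (374 against 55.9; 6.31–7.09), and the guidance receptor ROBO2 stood at 4673 against 1098 CPM (4.20–4.31 for the fold). Directions held in 8 of 8 libraries.

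Of 253 measured genes, 20 were higher in granule-like and 25 in pyramidal-like neurons, 208 were neither, and 7 of these passed 2-fold without every library. Among all 9273 genes measured, listed or not, 486 were higher in granule-like and 522 in pyramidal-like neurons. GABA-A subunits gave 2 of 12 in granule-like neurons and none in pyramidal-like: GABRG3 (782 against 201 CPM, 3.89-fold; 3.79–3.99) and GABRD (41.1 against 12.2, 3.37-fold; 3.02–3.77). GABRD joins receptors that carry tonic inhibition. Adhesion genes gave 3 and 1 of 17, vesicle genes 1 and 3 of 18, neurotrophin genes 2 and 3 of 8, and axon guidance genes 3 and 3 of 27. Pyramidal-like neurons also had more CNTNAP2 (3.19-fold), HOMER1 (2.89-fold), GRIK4 (2.87-fold) and NTRK2, the BDNF receptor (2.68-fold). Different clusters hold these types in different libraries. Of the granule-like clusters, cluster 5 took 99.7% of its nuclei from libraries 1 to 4 and cluster 24 took 99.5% from libraries 5 to 8, and pyramidal-like nuclei lay mostly in cluster 11 or in clusters 14, 27 and 28. The calls depend on where clusters are parted: 11 of the 45 ended at Leiden resolution 0.5. GABRG3 lost its call at resolutions 0.5 and 2.0 and with at least 1000 genes per nucleus (log2 ratio 2.21, 1.87 and 1.59). CACNA1G, higher in pyramidal-like neurons at 56.1 against 22.4 CPM, turned to a log2 ratio of 0.0063 at resolution 0.5, and stood near 0 in library 3. In the same setting the fold of NRP2 grew by over 1.5 times.

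Oligodendrocytes were compared with their precursors, since the exposures began in the first postnatal weeks, when the brain gains myelin. The membrane-shaping gene BIN1 was 12.7-fold higher in oligodendrocytes (11.5–14.1; 512 CPM), the netrin receptor UNC5C 8.44-fold (3021 against 358 CPM), the glutamate receptor GRM3 8.18-fold (611 against 74.7; 7.59–8.82) and the cholesterol enzyme IDI1 stood at 203 against 29.2 CPM (6.16–7.86 for the fold). Precursors had more NTNG1 (23.6-fold; 21.9–25.5), NTN1 (23.6-fold; 21.2–26.3) and the calcium channel gene CACNA1A (712 against 47.9 CPM; 13.9–15.9 for the fold). All 7 held in 8 of 8 libraries.

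Of 250 measured genes, 24 were higher in oligodendrocytes, 72 in precursors and 154 neither, 22 of which passed 2-fold without every library. Among all 9543 genes measured, listed or not, 782 were higher in oligodendrocytes and 1185 in precursors. Oligodendrocytes led for 8 of 14 cholesterol synthesis genes with none lower (median log2 ratio 1.69, percentile 100), and for 4 of 14 neurodegeneration genes (1 lower), among them APP (1181 against 547 CPM, 2.16-fold). Precursors led for 11 of 16 sodium and calcium channels (median −1.72, percentile 0), 10 of 16 AMPA, kainate and NMDA subunits, 7 of 14 vesicle genes, 7 of 18 adhesion genes (1 lower), 7 of 27 axon guidance genes (5 lower), 4 of 6 neurotrophin genes (1 lower) and 4 of 12 GABA-A subunits. GRM5, which couples glutamate to calcium release, stood at 1850 against 347 CPM (5.33-fold), and the sodium channel gene SCN1A was 10.7-fold higher. Among the GABA-A subunits were GABRB1 (668 against 103 CPM, 6.49-fold; 6.17–6.82), GABRA3 (98.8 against 18.3, 5.38-fold; 4.77–6.09; library 8 apart from the others) and GABRG3 (222 against 43.6, 5.09-fold; 4.70–5.51). The oligodendrocyte class includes cluster 36 (356 of 6207 nuclei), whose leading genes hold ENPP6, a marker of newly formed oligodendrocytes, and no oligodendrocyte marker. Libraries 5 to 8 held few oligodendrocytes, 1.12% to 1.49% of their nuclei. Weighting libraries equally brought GABRB1 to a log2 ratio of −1.90 and IDI1 to 2.14. Taking off 5% as free RNA, a step that can only widen a ratio, widened the folds of CACNA1A, GABRB1 and GABRG3 by over 1.5 times. TMM scaling shifted all genes by a median of 0.13 here.

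Astrocytes were compared with microglia, the 2 glial types that clear transmitter and mount immune responses. The GABA-B receptor subunit GABBR1 was 14.2-fold higher in astrocytes (818 against 57.7 CPM; 12.6–16.0), the glutamate receptor GRM3 stood at 1265 against 93.4 CPM (12.4–14.9 for the fold), and the GABA transporter SLC6A11 was 11.7-fold higher (194 against 16.6; 9.40–14.8). Microglia had 155-fold more IL18 (714 against 4.60 CPM; 125–196), 133-fold more of the complement gene C3 (478 against 3.59; 104–173) and 124-fold more of the potassium channel gene KCNK13 (286 against 2.30; 91.0–174). These held in the 6 libraries with at least 50 nuclei of both classes.

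Of 284 measured genes, 63 were higher in astrocytes, 33 in microglia and 188 neither, 18 of which passed 2-fold without every library. Among all 10609 genes measured, listed or not, 1582 were higher in astrocytes and 1401 in microglia. Astrocytes led for 8 of 15 Wnt and Notch genes (2 lower) such as TCF7L1 (18.4-fold; 15.3–22.3), 7 of 18 adhesion genes, 6 of 16 AMPA, kainate and NMDA subunits, 5 of 15 cholesterol genes, 4 of 9 chloride and GABA genes (1 lower) and 4 of 9 steroid and thyroid receptors (2 lower). NTRK2 stood at 2052 against 344 CPM and the lipoprotein CLU at 647 against 118. Microglia led for 8 of 13 complement and inflammatory genes (1 lower; median −5.68, percentile 0), 5 of 14 apoptosis genes, 4 of 12 heat shock genes and 3 of 15 neurodegeneration genes (4 lower), including BIN1 (372 against 24.9 CPM, 15.0-fold). Among GABA-A subunits, 3 of 11 were higher in astrocytes and 1 in microglia, GABRA3 (52.9 CPM, 4.08-fold). Microglia held fewer UMIs per nucleus than astrocytes (means of 1665 and 2315). Free RNA weighs more in such nuclei, and it was not tested as a source of the apoptosis, heat shock and GABRA3 calls. The astrocyte class rests on 3 clusters, each with over 90% of its nuclei from 4 libraries. TMM scaling shifted all genes by a median of 0.14.

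**Figure D3:**
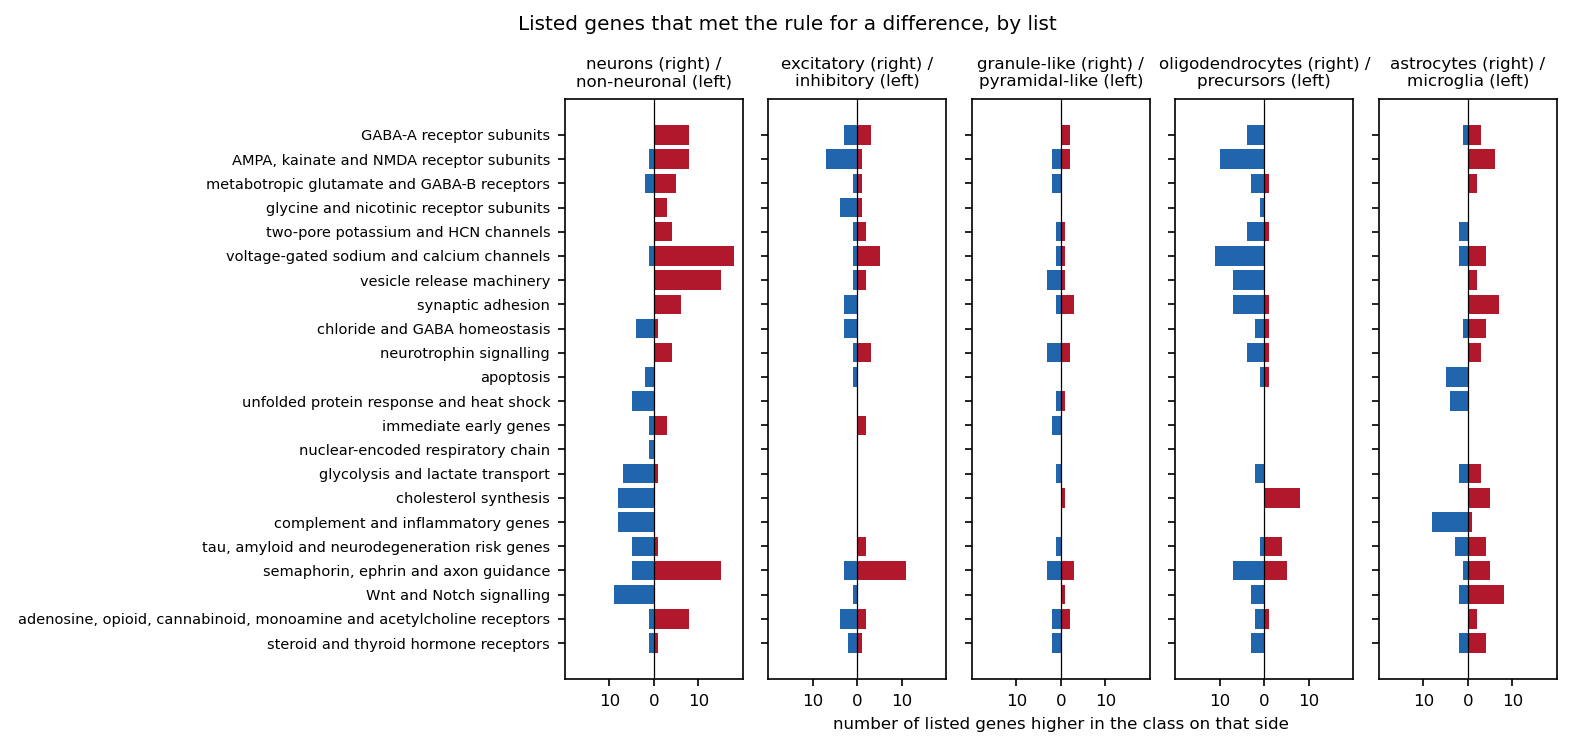
Number of genes per list that were at least 2-fold higher in the first or the second class with every library the same way, in 1 panel per comparison. Vesicle release genes (15 of 16) and sodium and calcium channels (18 of 22) lean to neurons, and complement genes to non-neuronal nuclei and microglia.

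The GABA-A subunits were then read across all classes. Neurons held more than non-neuronal nuclei of GABRA5 (5.70-fold), GABRA4 (4.87-fold), GABRB2 (379 against 83.1 CPM, 4.56-fold), GABRG3 (526 against 116, 4.52-fold) and GABRD (4.23-fold). GABRB1, at 827 against 802 CPM, was near even (1.03-fold, higher in neurons in 2 of 8 libraries), GABRA2 and GABRA3 were under 2-fold, and GABRG1 was 1.83-fold higher in non-neuronal nuclei. Astrocytes stood above both neuron classes for 3 subunits. GABRB1 reached 1892 CPM in astrocytes (1872–1913), against 871 in excitatory and 637 in inhibitory neurons, GABRA2 reached 506 (496–517) against 437 in excitatory neurons, and GABRG1 reached 234 against 57.0 in inhibitory neurons. Against microglia the astrocyte folds were 8.35 for GABRB1 (7.87–8.87), 5.26 for GABRA2 (4.80–5.78) and 9.32 for GABRG1 (7.80–11.2), the last from 1.59 to 13.1 over 6 libraries. These 3 subunits include an alpha, a beta and a gamma, the kinds that make up most receptors. Endothelial cells stood at 2375 CPM for GABRB1 (2299–2453), pooled over all 468 such nuclei, and at 1787 to 2544 in the 3 libraries with at least 50 of them. Both endothelial clusters had a median doublet score of 0.36, and doublets were not tested for this class. GABRA6, GABRP and GABRQ stayed under 10 CPM in every class. The gene given here as GABRB1 (ENSMMUG00000004314) takes its name from the symbol table, because the matrix's gene list names it differently and uses that name for more than 1 ID.

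**Figure D4:**
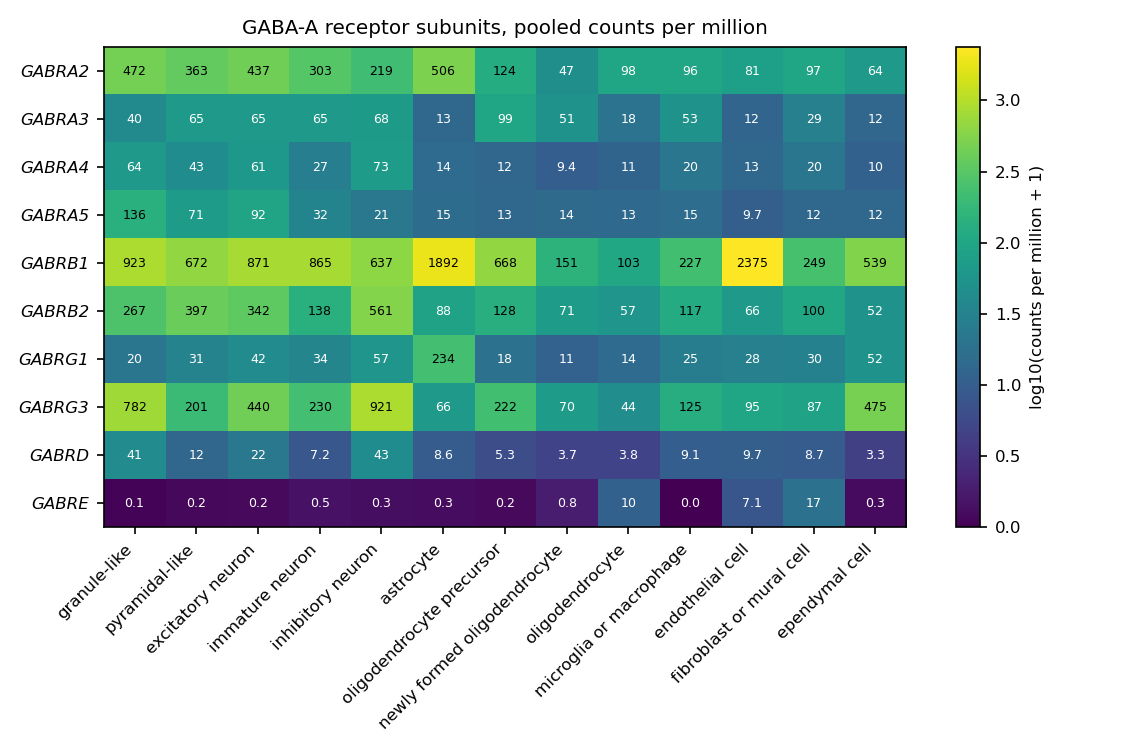
Pooled CPM of 10 GABA-A subunits that reached 10 CPM in at least 1 of 13 cell classes, printed in each cell and coloured by log10 of CPM plus 1. GABRB1, GABRA2 and GABRG1 stand at 1892, 506 and 234 CPM in astrocytes, each above excitatory and inhibitory neurons.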

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

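Of the tests here, only the reading of the low-UMI cluster was set before its result was seen; the tests of library shift, depth, scaling, and free RNA or doublets in astrocytes were chosen afterwards.

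In 8 of 218 sets of 8 library values, 1 library stood far from the other 7, where chance gives about 5% for independent values. The libraries are described as aliquots of 2 pools, not independent, so that rate is a guide only, and the share seen is below it. For neurons against non-neuronal nuclei, the log2 ratio of CACNA1B was 3.77 in library 6 (others 3.14 to 3.42) and that of NOTCH1 was −4.73 in library 3 (others −5.73 to −5.27). For granule-like against pyramidal-like neurons, KCNK9 was −3.43 in library 8 (others −2.68 to −2.02) and CACNA1G −0.11 in library 3 (others −1.13 to −0.77). For oligodendrocytes against precursors, SEMA4D was 4.67 in library 5 (others 3.03 to 3.76), GABRA3 −5.77 in library 8 (others −3.41 to −1.99), KCNK2 −0.12 in library 6 (others −4.31 to −2.61) and LRRTM4 −3.67 in library 5 (others −2.76 to −2.19). These values are computed with a count of 0.5 added, and libraries 5 to 8 held few oligodendrocytes.

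Class shares and clusters set the libraries apart: 16 of 19 excitatory and 3 of 3 astrocyte clusters took over 90% of their nuclei from 4 libraries, against 0 of 6 inhibitory clusters. All 3 oligodendrocyte clusters did so too, but the shares of that class fix this count in advance. Oligodendrocytes were 1.12% to 1.49% of nuclei in libraries 5 to 8 and 9.59% to 25.4% in libraries 1 to 4. Neuron shares of libraries 2 and 3 differed by 20.8 percentage points while their median UMI counts were within 10%, so the overall median alone does not set the share. That median mixes neurons with non-neuronal nuclei, which hold fewer UMIs. Depth within classes was therefore not matched, and depth per nucleus is not excluded. A shift of whole libraries acting alike in every cell type cannot be told apart from the rest, since the lowest mixing of libraries among inhibitory neighbours (an effective number of 3.87) was barely above the highest among excitatory (3.615) and astrocyte (3.61) neighbours, and all 3 classes lay below their shuffled values. Oligodendrocytes, few in libraries 5 to 8, lay above their shuffled values there by this number (3.44 to 3.60 against 3.17 to 3.31), yet by pairs of libraries all 4 classes kept some apart: neighbours fell to 0.033 of the expected share in excitatory neurons, 0.155 in inhibitory neurons, 0.012 in astrocytes and 0.096 in oligodendrocytes (shuffled, at least 0.951, 0.933, 0.9004 and 0.550). Depth within classes, dissection and differences between animals stay open, and no biological explanation was tested.

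Some heat shock, apoptosis and respiratory chain genes were called higher in non-neuronal nuclei: 5 of 12, 2 of 11 and 1 of 14, with the medians of the last 2 lists inside the range of random lists (percentiles 24.8 and 28.9). Free RNA, which weighs more in nuclei with little RNA of their own, may account for these calls. All 8 genes were higher still in the cluster with the fewest UMIs per nucleus, by a median ratio of 4.57. That cluster's markers scored highest for excitatory neurons (0.861). Excitatory neurons gave 179949766 of the 295564040 UMIs kept, so free RNA could score this way too. Whether the cluster holds more than free RNA is not settled by this score. Taking off 5% of the profile of all nuclei ended none of the 162 calls of this comparison, but it cannot decide the question. The same share came off both classes, which can only widen a ratio. Free RNA that weighs more in 1 class than in the other was not modelled. Under TMM factors, 7 of the 8 genes stayed at least 2-fold higher in non-neuronal nuclei. TMM adjusts counts already divided by the class totals, so it cannot exclude scaling to the same total as the cause. UMIs per nucleus were level for HSPA8 (0.199 in both classes) and higher in neurons for the other 7 genes, so the calls are differences of proportion. No biological explanation was tested.

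GABRA2, GABRB1 and GABRG1 stood high in astrocytes. Free RNA is excluded as the whole cause of the pooled values, since the lowest pooled ratio to oligodendrocytes or microglia was 5.17 (4.93–5.44). Single libraries went down to 1.59 for GABRG1 against microglia and 2.29 for GABRA2 against oligodendrocytes, each still above 1. Doublets with neurons are excluded as the whole cause for GABRB1 and GABRG1, since a mixture lies below the neurons. Their lowest pooled ratios to excitatory or inhibitory neurons were 2.17 and 4.10. For GABRA2 the lowest ratio was 1.16 (1.13–1.18), against the average of all excitatory neurons. Granule-like neurons held GABRA2 at a library median of 521 CPM, against 484 in astrocytes, so doublets with such neurons are not excluded for it. No biological explanation was tested, expression by astrocytes included.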

How the results depend on the processing

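Leaving out any 4 libraries was chosen after the data had been seen; the other alternatives were set before. Over all settings that keep every library, 3052 values of genes open to being named kept direction and side of the threshold, 58 fell short of a call, 19 gained one and 1 reversed. No minimum level and a 1.5-fold threshold cannot end a call. Taking off 5% as free RNA, which can only widen a ratio, ended none. The count of unchanged values therefore overstates how far the calls were tested. With each library left out, 2479 were the same, 21 fell short and 4 gained. CACNA1G, granule-like against pyramidal-like, reversed to a log2 ratio of 0.0063 at Leiden resolution 0.5. A 1.5-fold threshold gave 57 genes higher in excitatory and 58 in inhibitory neurons, 40 in granule-like and 41 in pyramidal-like neurons, by construction. Without any 4 libraries, genes higher in granule-like neurons reached 35 and in microglia 50. The shares of neurons, excitatory neurons, astrocytes and oligodendrocytes moved to 50.8%, 34.5%, 13.7% and 10.9% with every barcode, 56.0%, 38.7%, 13.4% and 11.7% with at least 1000 genes, 50.4%, 34.5%, 13.5% and 11.0% with doublets kept, and 60.9%, 40.6%, 15.0% and 5.54% as the median over libraries. At Leiden resolution 2.0, neurons were 50.8% and excitatory neurons 34.3%. With each library left out, neurons ranged from 49.9% to 56.5%, excitatory neurons from 33.7% to 38.3%, astrocytes from 13.7% to 14.7% and oligodendrocytes from 8.61% to 12.5%, and called genes numbered 99 to 105 for neurons, 60 to 65 for non-neuronal nuclei, 34 to 37 for excitatory, 34 to 36 for inhibitory, 18 to 23 for granule-like, 25 to 27 for pyramidal-like, 24 to 26 for oligodendrocytes, 70 to 76 for precursors, 61 to 67 for astrocytes and 32 to 37 for microglia. Where a share or a count moved or a direction reversed, the cause was not tested. The alternatives for sevoflurane against control (DESeq2, no filter on low counts, the replicate block, samples left out, doublets kept) were not run. No paired analysis was possible because no source used here ties a library to a sample. Depth limits genes of few UMIs: genes under 10 CPM in both classes were not measured, and classes with under 50 nuclei in a library gave no direction there.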

Other observations

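All values here were chosen after the data had been seen, and no test of a cause was run on them.

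The similarity of libraries was read from pooled gene counts, as a chi-square per gene between each pair, which ranged from 1.54 to 216 over 28 pairs. The nearest library of 1 was 2 (1.88), of 3 was 4 (2.04), of 5 was 7 (1.55), of 6 was 7 (1.54) and of 8 was 7 (1.57). By this measure the libraries fell into 3 sets, 1 and 2, 3 and 4, and 5 to 8: pairs within a set reached at most 2.04, and pairs across sets were at least 59.2. The larger split was of 1 to 4 against 5 to 8 (101 to 216), with 1 and 2 against 3 and 4 at 59.2 to 63.0. Neuron shares of libraries 1 to 8 were 49.4%, 50.7%, 29.9%, 30.6%, 71.9%, 71.0%, 71.9% and 71.7%. Oligodendrocyte shares in the same order were 10.0%, 9.59%, 25.4%, 24.4%, 1.12%, 1.49%, 1.29% and 1.46%, and immature neurons 9.56%, 9.90%, 3.18%, 3.21%, 0.306%, 0.157%, 0.242% and 0.459%. The labels describe 2 pools divided into 4 samples each, 1 mixed from 2 control animals and 1 from 1 exposed animal. From aliquots of 2 pools, 2 sets of like libraries would follow. The larger split has 4 libraries on each side, as described, while the smaller one is not in the description. Its cause is not resolved here, and these values give no group to any library. Pairs of libraries shared 8 to 32 barcode sequences.

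Some listed genes stood highest in classes that were not compared on their own, though they are part of the neurons or the non-neuronal nuclei compared above. In immature neurons (cluster 6 alone, with PROX1 and no immature marker among its 10 leading genes) the guidance receptor DCC reached 6141 CPM, 3.71-fold above excitatory neurons as a whole and with granule-like neurons at 2130, SEMA3A 282 (4.37-fold above the next class), NTF3 121 (granule-like neurons 89.0) and the glycine receptor subunit GLRA2 298 (2.95-fold). Newly formed oligodendrocytes had the AMPA receptor subunit GRIA2 at 4897 CPM (precursors 1433, pyramidal-like neurons 1589) and TCF7L2 at 161 (3.05-fold). Endothelial cells led for the lactate carrier SLC16A1 (1012 CPM pooled, 21.9-fold, but 167 to 1279 over 3 libraries), the glucose carrier SLC2A1 (612, 537 to 615, 21.0-fold) and LEF1 (1103, 859 to 1729, 7.35-fold), and fibroblasts or mural cells for the potassium channel gene KCNK2 (673, 11.0-fold, 310 to 929 over 5 libraries) and NR4A1 (176, 6.83-fold, 51.6 to 254). Median doublet scores were 0.36 in both endothelial clusters and 0.38 in the fibroblast or mural cluster, the highest among named clusters. Doublets were not tested for these classes. The gene ENSMMUG00000017395, FIP1L1 in the files and PDGFRA in the symbol table, stood at 1210 CPM in oligodendrocyte precursors and 982 in cycling cells, against 222 to 466 elsewhere.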
